A study of Homo sapiens with 2 samples.

How the data were processed

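Embryoid bodies from the H7 line were collected at day 21 under vehicle or 10 µM nicotine. Libraries were made with the 10x Genomics 3′ v2 chemistry, per the labels' protocols. The deposited values were raw UMI counts per gene and cell barcode for 33694 genes, made with Cell Ranger on hg38, per the submitters' processing notes, which also name Seurat. Versions and alignment settings are not given in the sources used here. The deposited barcodes were already limited to called cells, with a minimum of 3507 UMIs in the control and 4310 in the nicotine library. Such limits and the deeper nicotine library can move values of scarce genes and per-cell scores. The labels speak of 2 differentiation experiments, but all barcodes of a library carry 1 suffix, so cells could not be assigned to an experiment and each library was treated as 1 sample. No annotation of cell types was used.

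Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which removed 229 control and 264 nicotine barcodes. Scrublet's own threshold called 11 barcodes in each library, 0.161% and 0.195%, and was not used. Likely doublets were the highest-scoring barcodes at 0.8% per 1000 barcodes in a library, and 363 control and 238 nicotine barcodes were removed in addition. The kept cells held 68417075 and 73246240 UMIs, with medians of 9396 and 12241 per cell.

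Both libraries were clustered together without integration, after scaling to 10000 UMIs per cell and log transformation, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.8. This gave 15 clusters. They were named from markers of 14 classes. A marker counted as raised at 10 CPM or more and at least 1.25 times the mean over clusters. A name needed at least 3 raised markers, a share of raised markers at least 1.5 times that of the next class, the highest mean log2 fold of its markers among the classes, and no more markers of another class than of its own among the top 10 genes. These naming thresholds were chosen after the data were seen, among several rules considered. Cluster 4 was named on 3 raised markers of 12. A marker set among these is not reported here.

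UMIs were summed per library, and per class or cluster with at least 100 cells in each library, and scaled to CPM, UMI counts per total of 1000000. Levels carry exact Poisson intervals, ratios exact conditional intervals and shares exact Clopper-Pearson intervals, all at 95%. Each covers counting error only. The named genes in all cells were up to 10 in each direction with at least 50 CPM in either library and 1.5-fold apart, at a pseudocount of 5 CPM. In each class they were up to 5 in each direction, without markers of other classes and without genes under 0.1 of their level in another class in the library where the gene is higher, which free RNA can set. The extension of this rule to numbered clusters was chosen after the data were seen. Up to 4 members of each list with the largest change were also open to naming. For each of 25 gene lists, the median log2 ratio of nicotine over control was taken over members with at least 10 CPM, at a pseudocount of 1, and placed among 10000 random lists of the same size matched on mean expression. Lists were described as standing apart at percentile 0.5 or below or 99.5 or above with a median of at least 0.1 in size, a threshold chosen after the data were seen. Cell cycle phases were called after thinning each cell to 3000 UMIs.

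The markers, gene lists, filters, rule for named genes and 31 alternatives were set before the data were examined, and 10 alternatives were added later. The alternatives changed the filters, doublets, clustering, integration, scaling, expression minimum, pseudocount, thinning and weighting of clusters, and left out the cell with the most UMIs of a named gene in each library, the cells with the most UMIs of a list, or list members that free RNA can set in a class, all chosen after the data were seen. The weighting used all 15 clusters. Gene positions and shared exonic bases came from GENCODE release 29 on GRCh38, in which 33132 of the 33694 gene identifiers were matched. A further check of RPS10 by pseudogene counts was void, since too few genes could be matched.

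The estimates were tested on simulated data with 200 of 2082 genes changed by known folds. The test was first a single draw and failed, because intervals covered the true value for 82% of the 50 genes changed 1.5-fold, under the bound of 85% set for it. It was then averaged over 20 draws with that draw included, a change made after the failure was seen. Intervals covered the true value for 95.1% of unchanged genes and for 95.5% at 1.25-fold, 94.7% at 1.5-fold, 94.7% at 2-fold and 93.7% at 4-fold. The counts were drawn with counting error only, as the intervals assume. This coverage therefore checks the calculation and cannot show that the intervals are wide enough for real libraries. Over 2137 genes in all cells, the measured log2 ratios had a standard deviation of 0.10, against 0.024 expected from counting. The mean absolute error of the log2 ratio was 0.03 at 1.5-fold and 0.19 at 4-fold, where the pseudocount lowers it. Of 100 unchanged lists, 2 fell beyond the 2.5 or 97.5 percentile, and a list of 20 genes shifted 1.25-fold lay at percentile 100. These lists were random genes with independent counting error. They cannot show how often a list of genes that vary together reaches an extreme percentile between any 2 libraries.

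Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 with its Scrublet, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9 and Seurat 5.3.0 were used.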

Results

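Single-cell transcriptomes were measured in embryoid bodies grown from H7, an established human embryonic stem cell line. Embryoid bodies are free-floating aggregates in which pluripotent cells differentiate without a directed protocol. The labels describe 2 conditions at day 21, a vehicle control and culture with 10 µM nicotine, the tobacco alkaloid that activates nicotinic acetylcholine receptors. Each condition had 1 droplet library made with the 10x Genomics 3′ v2 chemistry. The question the design poses is how gene expression and cell makeup differed between control and nicotine-exposed embryoid bodies. The control library held 6847 barcodes with 75634236 unique molecular identifiers (UMIs), and the nicotine library held 5646 barcodes with 80289900 UMIs. The median barcode had 9437 UMIs and 2495 detected genes in the control library, and 12201 UMIs and 2896 genes in the nicotine library. After removal of barcodes rich in mitochondrial UMIs and of likely doublets, 6255 control cells and 5144 nicotine cells remained.

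With 1 library per condition there was no replicate, so no test across samples was possible and no p-value is given. Cells of a library are not replicates. Every interval below covers counting error only, and every difference is a difference between these libraries.

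Pluripotent-like and neural progenitor-like cells were the main named classes in both libraries. Clusters left unnamed together held 42.5% of control and 38.5% of nicotine cells, a difference of −3.94 percentage points. Pluripotent-like cells (clusters 1 and 10) carried the core pluripotency factor POU5F1 at 994 CPM (UMI counts scaled to a total of 1000000) in the control and 1009 in the nicotine library, with TDGF1, a Nodal co-receptor, at 314 and 302. Neural progenitor-like cells (clusters 2, 4, 5, 12 and 13) carried SOX2 at 514 and 503, the forebrain and eye field factor PAX6 at 149 and 126, and LHX2 at 118 and 112 CPM. Pluripotent-like cells made up 23.4% of control cells (exact binomial 95% interval 22.3 to 24.4%) and 21.4% of nicotine cells (20.3 to 22.6%), a difference of −1.97 percentage points, which ranged from −3.97 to −1.75 under other filters and clusterings. Neural progenitor-like cells made up 33.3% (32.1 to 34.4%) and 39.1% (37.7 to 40.4%), a difference of 5.80 points. The neural progenitor-like difference depended on the clustering and was 0.385 points after canonical correlation integration of the libraries and 0.493 points at a coarser resolution. The shares themselves moved far beyond their counting intervals between settings. Pluripotent-like cells were 20.3% of control cells with up to 20% mitochondrial UMIs allowed, and 35.9% with at least 1000 genes. Neural progenitor-like cells were 8.31% of control cells at the coarser resolution and 44.6% with doublets kept. Clusters 3 and 6 expressed neural progenitor markers but were left unnamed by a rule completed after the data were seen, because a gene fixed as a marker of another class was among the leading genes of each. Cluster 3 held 13.5% of control and 10.5% of nicotine cells, and cluster 6 held 8.51% and 8.63%. Counting both with the neural progenitor-like class gave 55.3% and 58.1%.

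**Figure D1:**
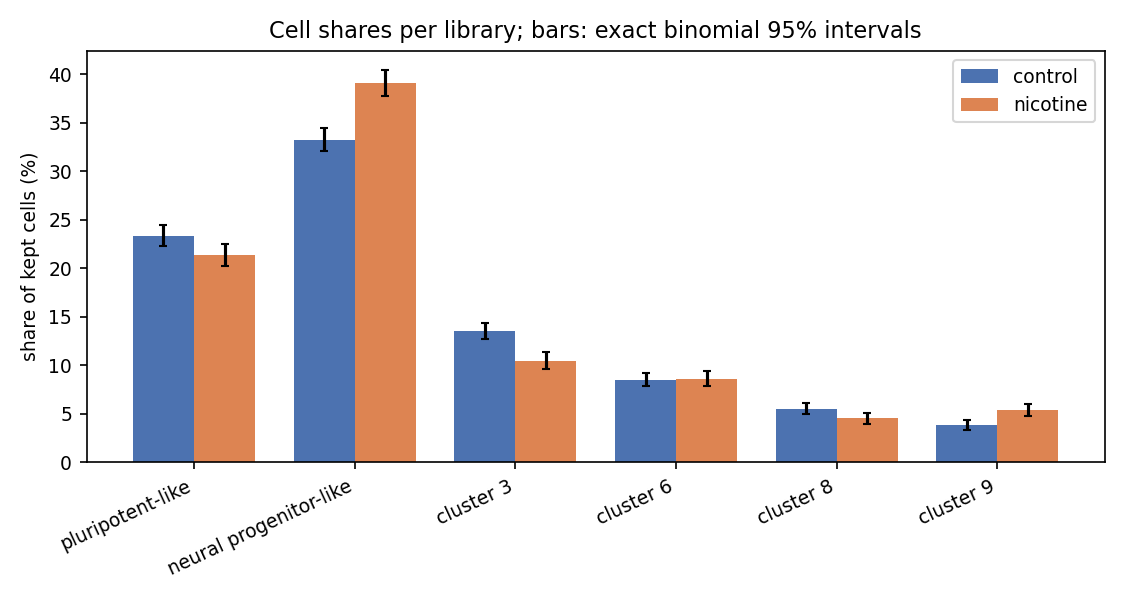
Share of kept cells, in percent, in the named classes and numbered clusters whose sizes were compared, for the control and nicotine libraries, with exact binomial 95% intervals. The neural progenitor-like class was larger in the nicotine library (39.1% against 33.3%) and cluster 3 was smaller (10.5% against 13.5%).

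Cluster 8 was led by LMO1, the retinoic acid hydroxylase CYP26A1 and the forebrain factors LHX5 and HESX1, and held 5.52% of control and 4.53% of nicotine cells. In it 8 of 10 pluripotency markers counted as raised against the mean over clusters. Their mean log2 fold over the rest of the cells was −0.040, however. POU5F1 was at 407 and 457 CPM there, against 439 and 412 over all cells. Cluster 9 was led by HAPLN1, DLX5 and GATA3, with raised epithelial markers, and held 3.85% (3.39 to 4.36%) and 5.38% (4.78 to 6.04%). Clusters 7, 11, 13, 14 and 15 had leading genes more than 1.5-fold apart between the libraries, so their sizes were not compared. Cluster 14, the epithelial-like class, was among them. That class held 0.879% of control cells, or 8.73% with doublets kept. Cluster 13 belongs to the neural progenitor-like class, whose difference without it was 4.72 points.

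Expression over all cells was closely alike in the libraries. Among 2137 genes with at least 50 CPM in either library, the middle 95% of log2 ratios of nicotine over control lay between −0.18 and 0.19, and Pearson's r across genes, which are not independent replicates, was 0.998. The rule for named genes, at least 1.5-fold apart at 50 CPM or more, took 7 genes that were lower in the nicotine library and 0 that were higher. These were the metallothionein genes MT1G, MT1E, MT1X and MT2A, the mitophagy gene BNIP3, the glucose transporter gene SLC2A1 and the interferon-induced membrane protein gene IFITM1. IFITM1 shares 32.5% of its exonic bases with IFITM2 in the annotation, so its count is uncertain.

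Metallothioneins, small cysteine-rich proteins that bind zinc and copper, were lower in the nicotine library as a group. All 6 measured members were lower, 5 of them by at least 1.5-fold, and the median log2 ratio of nicotine over control was −0.70, below all 10000 random lists matched on expression. MT1X (ENSG00000187193, GRCh38 chromosome 16, 56682424 to 56684196) had 636 CPM in the control and 383 in the nicotine library, a ratio of 0.603 (0.594 to 0.612). MT2A (ENSG00000125148, chromosome 16, 56608199 to 56609497) had 277 and 175, a ratio of 0.630 (0.616 to 0.644). MT1G had 254 and 137, a ratio of 0.539 (0.526 to 0.553), and MT1E had 181 and 103, a ratio of 0.572 (0.555 to 0.588). These genes are close paralogs, so the split of reads between them is uncertain. The list's median was below 0 in 8 of 8 classes or clusters, which are not separate observations, since free RNA from cells with high levels can enter all of them. It stayed below 0 in 8 of 8 without members under 0.1 of their level in another class or cluster, a check chosen after the data were seen, although only 2 members remained in clusters 3 and 6. The full list's median was −0.53 in pluripotent-like cells and −0.62 in neural progenitor-like cells, or −0.60 there over the 3 members that remained. It ranged from −1.31 in cluster 7 to −0.063 in cluster 11. In cluster 11 it lay inside the range of most random lists at percentile 11.7, MT1G and MT1H were higher and the list's mean was 0.054. That value depended on a few cells. Without the 10 cells with the most UMIs of the list in each library, the cluster 11 median was −0.76, with 6 of 6 lower. Those 10 cells were a larger share of the 152 nicotine than of the 211 control cells there. Leaving them out can therefore itself lower the ratio, and this value does not show a decrease hidden by a few cells. In cluster 7 the list includes MT1G and MT1H, which were among the genes that define that cluster. In pluripotent-like cells MT1X stood at 1138 CPM in the control and 715 in the nicotine library. In cluster 7, where keratin genes and pluripotency markers were both expressed, MT2A stood at 738 and 286, a ratio of 0.388 (0.367 to 0.409).

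Genes of glycolysis and the hypoxia response were also lower in the nicotine library. Of 17 measured members, 15 were lower, 3 of them by at least 1.5-fold, and the median log2 ratio was −0.19, below all 10000 random lists. BNIP3 (ENSG00000176171, chromosome 10, 131966455 to 131982013) had 279 CPM in the control and 169 in the nicotine library, a ratio of 0.606 (0.592 to 0.620). SLC2A1 (ENSG00000117394, chromosome 1, 42925375 to 42959176) had 103 and 64.5, a ratio of 0.627 (0.605 to 0.651). The prolyl hydroxylase subunit gene P4HA1 had 23.1 and 13.7, a ratio of 0.593 (0.547 to 0.642), and the hexokinase gene HK2 had 15.03 and 10.5, a ratio of 0.698 (0.635 to 0.767). The 2 higher members, named after their values were seen, were the glycolytic enzyme genes GAPDH, at 4592 and 5042, and ENO1, at 1114 and 1163. The list's median was below 0 in 8 of 8 classes or clusters, and lowest in cluster 3 at −0.60, where LDHA, the lactate dehydrogenase gene, had 691 and 430 CPM. In that cluster mitochondrially encoded genes were higher, with a median of 0.43 and 11 of 12 higher, and the median mitochondrial share of UMIs was 1.75% in the control and 2.41% in the nicotine library. In pluripotent-like cells the median was −0.089, and BNIP3 stood at 321 and 204. In neural progenitor-like cells the median was −0.15, and −0.31 in that class from centred libraries. With members limited to at least 50 CPM, the median was −0.077 over all cells and −0.036 in either class.

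**Figure D2:**
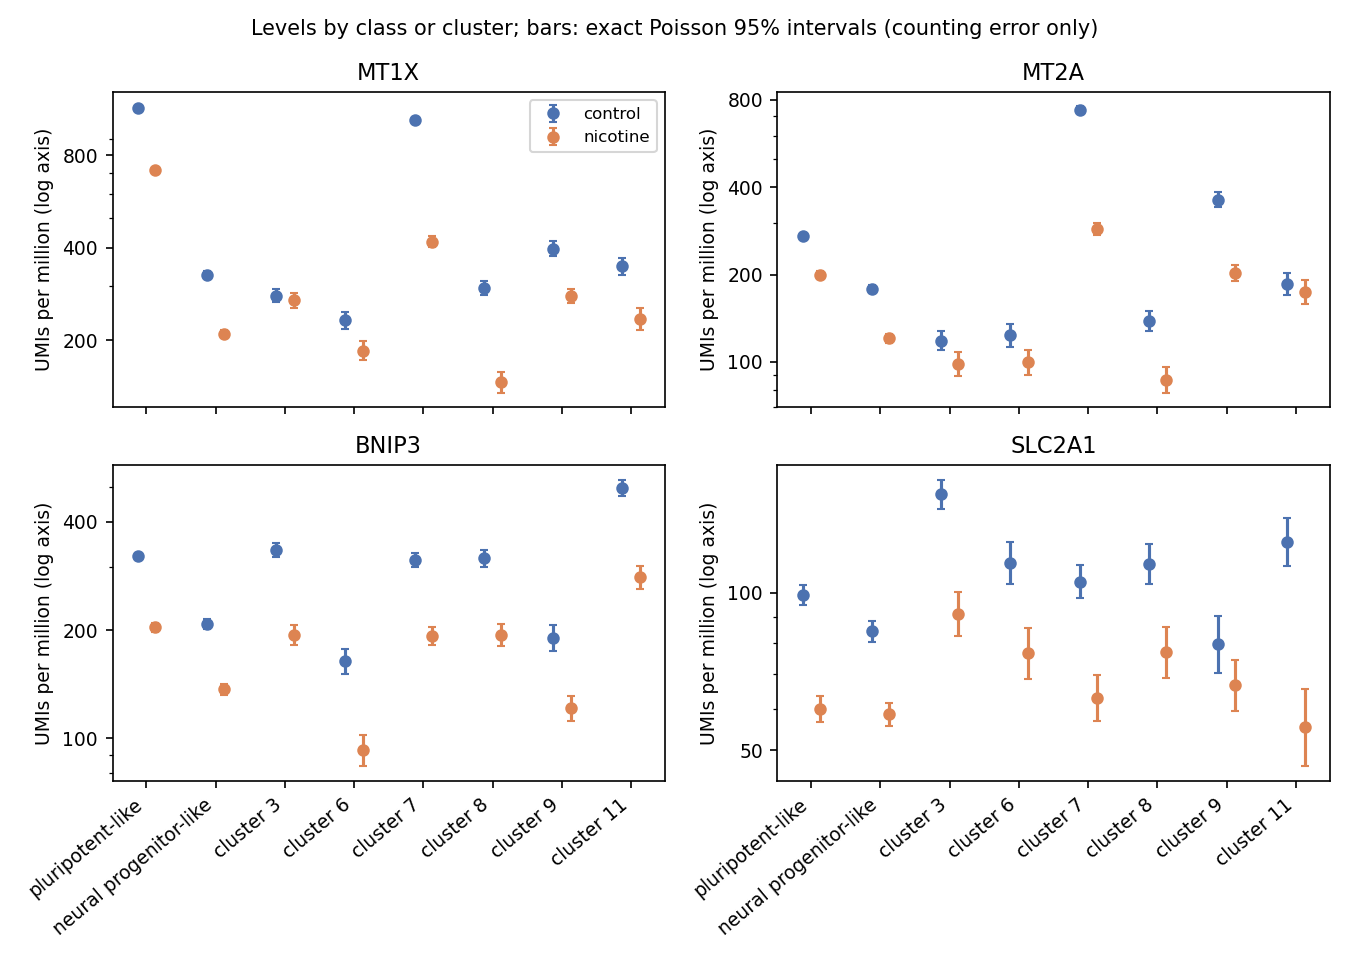
CPM on a log axis of the metallothionein genes MT1X and MT2A, of BNIP3 and of SLC2A1 in the control and nicotine libraries, by named class or numbered cluster, with exact Poisson 95% intervals. Each pair of points has the nicotine value below the control value. Examples are 738 against 286 for MT2A in cluster 7, 1138 against 715 for MT1X in pluripotent-like cells and a near tie at 279 against 270 for MT1X in cluster 3.

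Genes of DNA replication were higher in the nicotine library. Of 35 measured S phase genes, 33 were higher and none by 1.5-fold, with a median log2 ratio of 0.16, above all 10000 random lists. UHRF1, which maintains DNA methylation at replication, had 13.8 and 19.96 CPM, a ratio of 1.45 (1.33 to 1.58). PCNA, the replication sliding clamp, had 66.2 and 80.3, a ratio of 1.21 (1.17 to 1.26), and the ribonucleotide reductase gene RRM2 had 34.1 and 41.2. The median was above 0 in 8 of 8 classes or clusters, at 0.12 in pluripotent-like and 0.17 in neural progenitor-like cells. With each cell thinned to 3000 UMIs, 16.7% (15.8 to 17.7%) of control cells and 21.3% (20.2 to 22.5%) of nicotine cells were called S phase. Without thinning the shares were 21.5% and 28.5%. No cell was left out by the thinning. S phase shares were higher in the nicotine library in 7 of 7 classes or clusters examined, which left out cluster 11. The difference was 1.58 points in pluripotent-like cells and 12.7 points in cluster 6. The counting intervals of the libraries were apart in neural progenitor-like cells and cluster 6. They overlapped in pluripotent-like cells (17.5 to 21.6% and 18.7 to 23.6%) and in clusters 3, 7, 8 and 9. Because 23.0% of cells lay close to a boundary between phases, and free RNA can enter such calls, the shares describe scores rather than cycling cells. Genes of G2 and M phase had a median of 0.038, with 40 of 51 higher. The direction differed between classes. The median was 0.076 in pluripotent-like cells, with 40 of 51 higher, and −0.098 in neural progenitor-like cells, with 39 of 51 lower, and it was above 0 in 4 of 8 classes or clusters. Cluster 5, which is led by genes of these phases, was 27.2% of neural progenitor-like cells in the control and 25.7% in the nicotine library, and the median of that class was −0.080 with its clusters weighted alike. Cells called G2/M made up 40.02% of control and 41.0% of nicotine cells, a difference within the counting intervals.

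Heat shock and chaperone genes were higher in the nicotine library, with 8 of 10 measured members higher and a median log2 ratio of 0.20, above all 10000 random lists. HSP90AA1 had 1312 and 1551 CPM, a ratio of 1.18 (1.17 to 1.19), and HSPA8 had 537 and 618, a ratio of 1.15 (1.14 to 1.17). HSPA1A, the inducible member, had 16.8 and 20.6. The paralogs HSPA1A and HSPA1B can share reads. The list's median was above 0 in 8 of 8 classes or clusters, at 0.12 in pluripotent-like and 0.19 in neural progenitor-like cells. In cluster 11 it was 0.19, but 0.032 without the 10 cells with the most UMIs of the list in each library. As for metallothioneins, leaving these cells out can itself lower the ratio there. Immediate early genes were lower, in 6 of 6 measured members, with a median of −0.14 at percentile 0.12 of the random lists, or −0.063 with members of at least 1 CPM. ATF3 had 13.5 and 10.4 CPM, or 7.56 and 7.29 outside cluster 11, and IER2 had 112 and 101. The immediate early median was above 0 in 2 of 8 classes or clusters, at 0.11 in cluster 6 and 0.0036 in cluster 9, and lowest in clusters 8, 11 and 7 at −0.26, −0.24 and −0.22. It was −0.080 in pluripotent-like cells and −0.091 in neural progenitor-like cells, inside the range of most random lists at percentiles 12.3 and 12.97. Without members that free RNA can set, the median was above 0 in 1 of 8. Cluster 9 was then at −0.15, cluster 8 at −0.11 over 3 members, and cluster 7 was lowest at −0.22. Cluster 11 was at −0.40 without the 10 cells with the most UMIs of the list in each library, a removal that can itself lower the ratio.

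**Figure D3:**
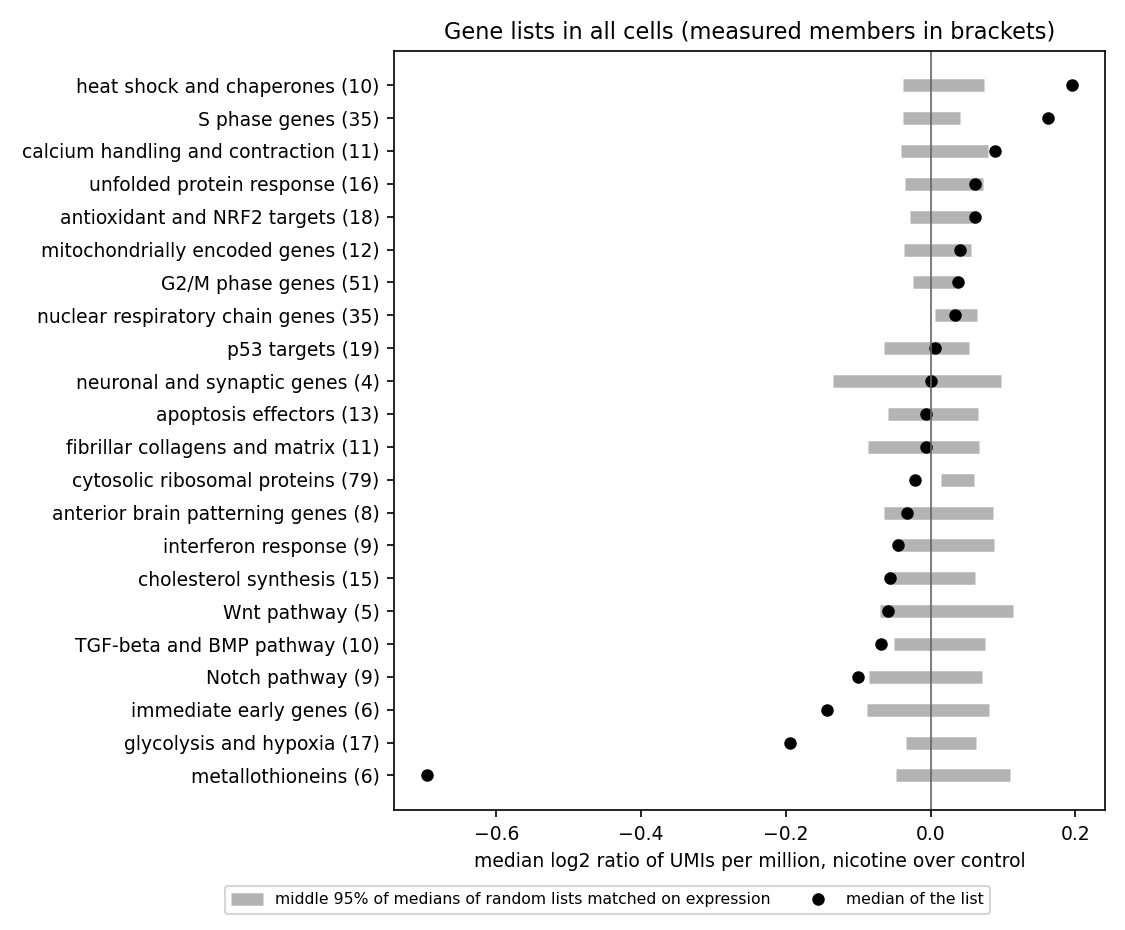
Median log2 ratio of CPM, nicotine over control, for the 22 gene lists with a percentile in all cells (points), with the middle 95% of medians of 10000 random lists matched on expression (grey bars) and measured members in brackets. Metallothioneins at −0.70 and glycolysis and hypoxia at −0.19 lie left of their bars, and S phase genes at 0.16 and heat shock genes at 0.20 lie right of theirs.

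The other lists showed smaller differences over all cells. The p53 targets had a median of 0.0066, with 10 members higher and 9 lower, and GDF15 at 30.3 and 21.3 CPM. That median was above 0 in only 2 of 9 alternative settings and was −0.13 with members of at least 50 CPM. Apoptosis effectors had a median of −0.0065, below 0 in 6 of 9 settings, and BNIP3 was their only member at least 1.5-fold apart. Antioxidant and NRF2 target genes were at 0.061, with 14 of 18 higher and NQO1 at 18.3 and 21.8. The unfolded protein response was at 0.062, with 13 of 16 higher, although DDIT3, a stress-induced transcription factor, was lower at 37.4 and 24.4. DDIT3 and GDF15 lead cluster 11, and outside that cluster DDIT3 was at 14.8 and 12.4 and GDF15 at 6.76 and 5.77. Mitochondrially encoded genes were at 0.041 over all cells, but at 0.56 in cluster 11, 0.43 in cluster 3 and 0.18 in cluster 6, each above all 10000 random lists. In cluster 11 the median cells were alike, and the upper quartile of the mitochondrial share was 0.967% in the control and 2.36% in the nicotine library. Nuclear respiratory chain genes were at 0.033. Calcium handling and contraction genes were at 0.089, with the actin genes ACTA1 at 11.7 and 19.1 and ACTC1 at 23.2 and 32.7. Fibrillar collagens and matrix genes were at −0.0066, or 0.050 with members of at least 1 CPM, with fibronectin (FN1) at 9.44 and 13.4 CPM. Notch pathway genes were at −0.10, or −0.0017 with members of at least 50 CPM, Wnt pathway genes at −0.059, or −0.12 with class shares standardised, and TGF-beta and BMP pathway genes, with BMP4 at 31.4 and 26.9, at −0.069, or 0.021 as a mean of per-cell values. Anterior brain patterning genes were at −0.033, and cholesterol synthesis at −0.056, or 0.078 with members of at least 50 CPM. Interferon response was at −0.045, or 0.026 in cells with at least 1% mitochondrial UMIs, with ISG15 at 91.9 and 79.8. ISG15 was at 638 and 222 in cluster 11, where 1 control cell held 568 of 1810 UMIs. Cluster 11 held 1810 of the control and 554 of the nicotine UMIs of ISG15. Its lower value over all cells rests on that cluster, since outside it ISG15 was higher in the nicotine library. Neuronal and synaptic genes were at 0.00032, above 0 in 7 of 9 settings. Cytosolic ribosomal protein genes were at −0.022, with 56 of 79 lower. That median lay below all 10000 random lists, and the median over the 2137 genes with at least 50 CPM was 0.025. In single classes or clusters some of these lists, and the G2 and M phase list, stood further apart, in 14 cases by the threshold for lists. Apart from the mitochondrially encoded genes, the largest in size were interferon response in cluster 11 at −0.42, with 9 of 13 lower, or −0.28 without the 10 cells with the most UMIs of the list in each library, and TGF-beta and BMP genes in cluster 7 at −0.28, with 9 of 10 lower.

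Genes of nicotine sensing were scarce. Of 16 nicotinic acetylcholine receptor subunit genes, 12 were under 1 CPM over all cells in both libraries and none reached the minimum of 10 there. Within single clusters, 1 subunit reached 10 CPM in each of clusters 3, 6, 8 and 11, and 2 did in cluster 9. Their median log2 ratios ranged from −0.43 in cluster 6 to 0.18 in cluster 9. Over all cells the levels were as follows. CHRNB1 was at 8.49 and 8.85, CHRNA5 at 6.53 and 7.45, CHRNA3 at 1.40 and 1.24, and CHRNA7, the subunit of the homomeric receptor, at 1.04 and 0.82 CPM. In the list of nicotine and xenobiotic metabolism, CYP1B1 was at 25.9 and 29.3 and the reductase gene POR at 26.3 and 27.1, and the median of these members was 0.11.

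Within classes and clusters the same rule was applied. It also took 2 genes that lead their own cluster and are not listed again below. They were MT1G in cluster 7, at 799 and 376 CPM, and APOA2 in cluster 11, with 319 of its 326 nicotine UMIs in 1 cell. In pluripotent-like cells the named genes were SLC2A1, MT1X, MT1G and BNIP3, each lower in the nicotine library, and in neural progenitor-like cells MT1X and BNIP3. Cluster 3 had BNIP3, SLC2A1, SLC2A3, LDHA and FAM162A lower, with PCNA higher at 32.1 and 55.4 CPM and ACTC1 higher at 29.03 and 67.2, or at 22.5 and 38.4 without the cell with the most ACTC1 UMIs in each library. Cluster 6 had BNIP3 and LDHA lower and the cycle genes ZWINT and CHAF1A higher. Cluster 8 had MT1X at 296 and 146, with SLC2A3, BNIP3, FAM162A and MIAT also lower. In cluster 9 MT1G, CYR61, MT1E, MT2A and COL2A1 were lower, and DDIT4, a stress-induced inhibitor of mTOR signalling, was higher at 89.0 and 156. Of these, MT1G and COL2A1 in the nicotine library and DDIT4 in the control were under 0.1 of their level in another cluster, where free RNA can set the value. Cluster 7 had TUBB2A higher at 28.3 and 53.8, and MT2A, MT1E at 573 and 227, MT1X at 1040 and 419, and MT1F at 85.1 and 46.1 lower. Cluster 11, a group of cells with 0.230% and 0.238% median mitochondrial UMIs and led by the stress genes GDF15 and DDIT3, had POU5F1 at 821 and 807 CPM. The named gene with the lowest ratio there was the cyclin gene CCNA1, at 106 and 11.6, but only 8 control cells and 4 nicotine cells held its UMIs. The interferon-induced gene ISG15 was at 638 and 222, a ratio of 0.349 (0.317 to 0.384), with 568 of its 1810 control UMIs in 1 cell, and at 440 and 210 without the cell with the most ISG15 UMIs in each library. HILPDA was at 148 and 69.5 and SLC2A1 at 125 and 55.4, with RP11-265D19.6 also lower and CYP26A1, CNTNAP2 and ACTA1 higher. ACTA1 was not higher as a mean of per-cell values. TAGLN, a smooth muscle actin-binding protein gene, was at 97.2 and 204, and at 93.5 and 142 without the cell with the most TAGLN UMIs in each library, under 1.5-fold at the pseudocount of 5 CPM.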

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

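The tests at equal depth, and both tests over all members of the hypoxia list, were chosen after the result was seen.

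Barcodes with more than 10% mitochondrial UMIs were left out of every comparison. They made up 3.34% (2.93 to 3.80%) of control barcodes and 4.68% (4.14 to 5.26%) of nicotine barcodes, so this signal outside the main measurement was above the level in the control library. Over 20% mitochondrial UMIs, the shares were 1.07% and 1.90%. No explanation was tested.

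Metallothionein genes were lower in the nicotine library, with a median log2 ratio of −0.70. With both libraries weighted to the same cluster shares the median was −0.65 (−0.67 to −0.63). This argues against different cluster shares as the whole cause, and cannot speak to a different makeup inside clusters. MT1G and MT1H were themselves among the leading genes of cluster 7. In cells above the higher UMI minimum (4310), thinned to equal depth, the median was −0.79 (−0.84 to −0.73), which argues against the difference in depth. A difference in culture or handling other than nicotine cannot be told apart from the treatment, since there was 1 library per condition. An effect of nicotine stays open and untested.

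Hypoxia and glycolysis genes were lower in the nicotine library, with a median log2 ratio of −0.19 over 17 measured members. The median was −0.15 (−0.21 to −0.10) with cluster shares made equal and −0.16 (−0.28 to −0.12) at equal depth. These values argue against cluster shares or depth as the whole cause, and cannot speak to a different makeup inside clusters. These tests were first set up on HK2, SLC2A1, BNIP3 and P4HA1 alone, whose mean was −0.64, and −0.61 and −0.63 under those settings, and were restated for all members after these values were seen. Oxygen supply or other culture conditions may have differed, and 1 library per condition leaves that and an effect of nicotine open.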

How the results depend on the processing

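The alternatives at equal depth, in cells with at least 1% mitochondrial UMIs, and with clusters 3, 4, 6 or 13 moved into or out of a class, and for named genes without the cell with the most UMIs of the gene in each library, or for list medians by class without members that free RNA can set, without the cells with the most UMIs of the list or with the clusters of a class weighted alike, were chosen after seeing the data. The cause was not tested for any of the changes below, and a value counts as moved where it left its counting interval. No paired analysis was possible because there was 1 library per condition. Among list medians in all cells, 163 of the alternative values stayed within that interval, 40 moved and 3 reversed, where reversed means a change of sign in a median whose interval excluded 0. A further 13 values changed sign in 4 of the 5 lists whose interval included 0. They were p53 targets, which kept their sign in 2 of 9 alternatives, apoptosis effectors in 6 of 9, neuronal genes in 7 of 9 and matrix genes in 8 of 9. The number of genes at least 1.5-fold lower was 7 and ranged from 6 to 8, and the number higher was 0 under every alternative run. Without the cell with the most UMIs, 49 of 51 values of named genes stayed at least 1.5-fold apart at the pseudocount of 5 CPM, and APOA2 and TAGLN in cluster 11 did not. The pluripotent-like difference was below 0 in 9 of 9 alternatives and the neural progenitor-like difference above 0 in 12 of 12. No epithelial-like class was found at resolution 0.4, and no xenobiotic gene reached 50 CPM. Depth limits genes under 10 CPM, among them the nicotinic receptors over all cells.

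The pluripotent-like difference was −3.60 percentage points with up to 20% mitochondrial UMIs allowed, −3.74 with at least 1000 genes, −3.60 with doublets kept and −3.97 with 4000 variable genes. The limit of 1000 genes kept 6251 of 6255 control cells and all 5144 nicotine cells. The neural progenitor-like difference was 3.06 at 5% and 3.92 at 20% mitochondrial UMIs, 3.004 with doublets kept, 0.493 at Leiden resolution 0.4, 1.16 at 1.5, 1.13 with each library centred, 0.385 with Seurat CCA, 2.86 with clusters 3 and 6 and 3.31 without cluster 4. The S phase difference was 6.93 points not thinned and 6.28 with doublets kept.

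With median-of-ratios scaling the medians were 0.14 for S phase, 0.013 for G2/M, 0.036 for NRF2 targets, 0.016 for mitochondrially encoded, 0.0080 for respiratory chain and 0.064 for calcium genes, −0.72 for metallothioneins, −0.047 for ribosomal proteins, and 0.095 for heat shock genes in pluripotent-like cells. With a pseudocount of 5 the S phase median was 0.14. With class shares standardised S phase was at 0.14, G2/M at 0.018, mitochondrially encoded at 0.067, respiratory chain at 0.045, Wnt at −0.12, anterior brain at −0.11 and metallothioneins at −0.65. As means of per-cell values S phase was at 0.19, glycolysis at −0.26, mitochondrially encoded at 0.062, anterior brain at −0.063 and metallothioneins at −0.76 (−0.70 in pluripotent-like and −0.54 in neural progenitor-like cells), while TGF-beta reversed to 0.021 and ACTA1 in cluster 11 to −0.052.

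With members of at least 50 CPM G2/M was at 0.068, p53 targets at −0.13, glycolysis at −0.077, Notch at −0.0017, TGF-beta at −0.0022 and metallothioneins at −0.73, and cholesterol synthesis reversed to 0.078. In pluripotent-like cells glycolysis was then at −0.036, and in neural progenitor-like cells heat shock was at 0.26, glycolysis at −0.036 and metallothioneins at −0.56. At 1 CPM immediate early genes were at −0.063, xenobiotic at 0.040, calcium at 0.055, TGF-beta at −8.6e-05 and metallothioneins at −0.73.

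In cells with at least 1% mitochondrial UMIs heat shock was at 0.20, the unfolded protein response at 0.10 and mitochondrially encoded genes at 0.025, and interferon reversed to 0.026. At equal depth the unfolded protein response was at 0.097, xenobiotic at 0.22, Wnt at −0.12, metallothioneins at −0.79 and neuronal genes at 0.073. With doublets kept metallothioneins were at −0.71 in pluripotent-like and −0.53 in neural progenitor-like cells, where S phase was at 0.25 and glycolysis at −0.30. In classes from centred libraries metallothioneins were at −0.77 in pluripotent-like cells, and S phase was at 0.26 and glycolysis at −0.31 in neural progenitor-like cells. Without the 10 cells with the most UMIs of the list in each library, medians in cluster 11 were 0.70 for mitochondrially encoded genes, −0.28 for interferon response and −0.76 for metallothioneins. Heat shock genes there were at 0.032, with 6 higher and 4 lower, and immediate early genes at −0.40. Metallothioneins were then at −0.74, −1.76 and −1.13 in clusters 3, 7 and 8, further below 0 than before. In clusters 6 and 9 they were at −0.45 and −0.67, closer to zero than before. Of 42 pairs of a list and a class or cluster that stood apart, all 42 kept their sign without these cells, and 39 stayed at 0.1 or more in size. An equal number of cells is a larger share of the library with fewer cells, so this check is not neutral between the libraries. Clusters 3, 6, 7, 8 and 11 held fewer nicotine than control cells, where it can itself lower ratios, and cluster 9 held more.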

Other observations

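Both tests of RPS10 were chosen after the result was seen, as was the overlap threshold of 25%.

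Markers of mesoderm and endoderm were scarce in both libraries. Embryoid bodies often hold derivatives of these layers, and whether the libraries represent all cells of the cultures was not tested. Markers of blood summed to 1.199 CPM in the control and 1.65 in the nicotine library, and those of cardiac muscle to 5.58 and 6.12. Those of liver or yolk sac endoderm summed to 3.65 and 12.0, with APOA2 at 0.935 and 5.68, but 1 nicotine cell held 578 of the 879 UMIs. Without the cell with the most such UMIs in each library the sums were 3.63 and 4.11. Of the 9 endothelial markers measured, EGFL7 at 49.8 and 48.1 made up most of the sums of 55.2 and 53.2. Pluripotency markers summed to 1717 and 1620, epithelial markers to 1311 and 1330, and neural progenitor markers to 879 and 880. Markers of neurons summed to 52.0 and 56.0, of stroma to 26.4 and 29.9, and of skeletal muscle to 28.98 and 36.3. Those of ciliated cells summed to 32.4 and 31.02, of trophoblast to 20.02 and 16.3, and of pigmented retina or melanocytes to 149 and 159, with the melanosome gene PMEL at 123 and 136. All 29 HOX genes were under 1 CPM in both libraries.

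Some cells had almost no mitochondrial UMIs. Cells with under 1% made up 9.05% (8.35 to 9.79%) of control and 7.48% (6.78 to 8.24%) of nicotine cells, with a median of 6759 and 7665 UMIs. In cluster 10, led by KPNA2, CCNB1 and ZFP42, the median mitochondrial share was 0.166% in the control and 0.167% in the nicotine library. Its median cell had 4920 and 6374 UMIs, against 15418.5 and 20951 in cluster 1, the other pluripotent-like cluster.

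RPS10 (ENSG00000124614, chromosome 6, 34417454 to 34426125) had 442 CPM in the control and 592 in the nicotine library, a ratio of 1.34 (1.32 to 1.36), and was above 1.2 in 9 of 10 classes or clusters. The other 78 ribosomal protein genes had a median log2 ratio of −0.022, which argues against a shift of these genes as a whole as the cause of a value of 0.42. RPS10 shares 39.4% of its exonic bases with the read-through gene RPS10-NUDT3, and reads from shared exons may have been assigned differently in the libraries. The 32 other genes with at least 25% shared bases had a median of 0.089, at percentile 99.94 of random lists, and the percentile was 97.2 at a threshold of 5%, 99.83 at 10% and 90.87 at 50%, where 4 genes remained. PSMA2, with 14.6% shared bases, was at 0.42 and NDUFC2, with 16.3%, at 0.35. Both lie under the threshold of 25% and were chosen after their values were seen, so they are no test of this explanation. The median of the 32 genes is far below 0.42 and RPS21, with no shared bases, was at 0.22, so this stays a candidate explanation for part of the pattern, and no biological explanation was tested.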
